A study of Mus musculus with 18 samples.

How the data were processed

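RNA was measured in mouse skin flaps collected at day 7, per the labels' protocols. Total RNA was extracted with TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made with a VAHTS Universal V6 RNA-seq kit, per the labels' protocols. The deposited table holds FPKM values, fragments per kilobase of gene scaled to the library's counted fragments, for 27743 genes in 18 libraries, computed by the authors. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0, DESeq2 and the mm10 build, with no role or order. The gene annotation and whether counting used strand are not given in the sources used here. FPKM divides each library by its own total, so a few very abundant transcripts that differ between libraries shift all other values of that library.

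The FPKM values of a gene were whole multiples of the value of 1 fragment, within a relative tolerance of 1e-07, in all but 1 of the 27743 genes. Relative depth and fragments per library were recovered from these steps. Libraries held 28122056 to 34881279 recovered fragments, and the highest depth was 1.24 times the lowest. On simulated values the recovery was exact in 99.93% of 2975 genes.

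Groups and replicate numbers were taken from the sample titles and the group label. The groups are Control, D15L100, D15L150, D15L200, D100L150 and D150L150, with 3 libraries each. The labels do not say whether libraries of a group came from separate animals. The p-values thus measure only the spread between these libraries, which may be partly technical and need not be that between animals. Between 2 libraries of a group the chi-square per gene was 47.6 to 279.7, where counting chance alone gives about 1. These values argue against repeat sequencing of 1 library as its source. The labels give neither a unit nor a meaning for D and L, and none was assumed.

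Values were transformed to log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 3 of the 18 libraries were kept, which left 13078 genes and removed 14665. Fold changes are on this scale, which understates changes of low genes. A limma linear model (limma 3.58.1, R 4.3.3) with 1 mean per group was fitted to all 18 libraries, so that all groups share 1 estimate of the spread. Empirical Bayes moderation used a mean-variance trend and robust estimation, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Genes with an adjusted p under 0.05 were called. Each spacer group and the mean of the 5 spacer groups were compared with Control. Spacer groups that differ in 1 of the label numbers were compared with each other, in pairs and by a moderated F test over each series of 3 groups.

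The text names genes by a rule. For each comparison these are up to 10 genes in each direction with the largest change among called genes whose replicates do not overlap. For the mean of the spacer groups, all 5 group means had to lie on the same side of Control. Predicted genes were not named. For a gene list the 4 members with the smallest p were eligible, and for a series the 10 genes with the smallest p. Not all eligible genes are named, and 1 is not reported here. Members of other kinds, given as values per library, are said to be chosen after their values were seen.

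There were 42 gene lists, of which 41 were tested. The other holds sex-linked genes, used as a check of the libraries, in which Ddx3y lay at 10.95 to 30.22 FPKM and Xist at 0 to 0.011. Lists were tested with camera at a preset correlation between genes of 0.01, and with the correlation estimated per list. They were also tested with fry, which asks whether the genes of a list move on balance in 1 direction. For each library a list level was taken as the mean log2(FPKM + 1) of its members, and spacer libraries were compared with Control by a two-sided exact permutation test over 816 splits. Gene ontology terms came from the authors' annotation column. They were tested by a one-sided hypergeometric test for the called genes against 12849 annotated genes, over 3549 terms. This test takes genes as independent, so its p-values can be far too small for genes that vary together.

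The test was run on simulated data with the real means and spreads and 200 changed genes, over 5 runs of 13078 genes. In the simulated comparison of D150L150 with Control, 67.6% of the 2-fold and 92.8% of the 4-fold changes were recovered. For the mean of the spacer groups these shares were 79.4% and 95.2%, and for the series of 3 groups at L150 64.8% and 91%. Simulated genes were independent of each other and normally distributed, so recovery in real libraries can be lower.

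Samples, tests, lists, the naming rule and a first set of alternatives were fixed before the data were examined. These alternatives were a pseudocount of 0.1, no filter on low values, quantile scaling, rescaling to TPM, the replicate number as a block, a fit with only the groups compared, leaving out each library in turn, and the estimated correlation. Chosen after seeing the data were the lengths of the simulated lists of unchanged groups, fry without each library in turn, leaving out the 3 libraries with the highest cytokine level, the skeletal muscle level as a covariate, library weights, and voom on the recovered fragments. Gene positions were looked up by NCBI gene number in the RefSeq annotation of GRCm38, the assembly also called mm10, where all 77 genes looked up had a match. Figures were drawn with matplotlib 3.10.9.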

Results

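The series measured gene expression in mouse skin flaps collected at day 7. Mesh-like spacers, made by near-field electrostatic printing with different diameters and spacings, were placed under the flaps, and Control flaps were left untreated. The spacer groups are named here as labelled, D15L100, D15L150, D15L200, D100L150 and D150L150. The series' stated question is how topology regulates cell differentiation in place. Each of the 6 groups had 3 libraries with 28122056 to 34881279 recovered fragments, and 11778 to 12488 genes reached an FPKM of 1. All fold changes below are log2 differences of log2(FPKM + 1), with the standard error of the limma fit, and adjusted p-values are limma's with Benjamini-Hochberg adjustment over 13078 genes.

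Flaps over spacers, taken as the mean of the 5 spacer groups, had higher values than Control for genes of wound-activated and cornifying keratinocytes, by gene counts that rest on 1 of the 3 Control libraries. Krt6b, a keratin of activated epidermis at chromosome 15, 101676023 to 101680293 in GRCm38, averaged 207 ± 122 FPKM (SD, n = 3) in Control and 1660 ± 413 in D100L150. Across the 5 spacer groups Krt6b was higher by 2.40 ± 0.35 (SE, adjusted p = 0.00674 with limma). Krt6a was higher by 1.98 ± 0.26, Krt16 by 1.84 ± 0.28 and the gap junction gene Gjb2 by 2.28 ± 0.32. Krt6a and Krt6b are closely related in sequence, so their fragments can be split between them uncertainly. Of the 13 wound-activated keratinocyte genes tested, 10 rose, none fell and 3 did not pass, or 11 rose when adjusted over the list alone. Their median change was 1.96. The camera adjusted p was 2.24e-13, but adjusted p = 0.383 with an estimated correlation, and the fry adjusted p was 0.00353, which stayed under 0.05 without any 1 library. In the exact permutation test of list levels the difference was 1.71 with p = 0.00245, adjusted p = 0.0502.

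Among the genes eligible for naming, the largest rises in that comparison were in genes of the outer epidermis. Lypd5 rose by 3.22 ± 0.57, from 7.74 ± 5.51 FPKM in Control. The kallikrein-related protease genes Klk10, Klk6 and Klk5 rose by 3.05 ± 0.50, 2.82 ± 0.39 and 2.60 ± 0.48. Spink5, encoding an inhibitor of such proteases, rose by 2.69 ± 0.45. Cdsn, encoding corneodesmosin, rose by 2.86 ± 0.49, and Dsc1, a desmosomal cadherin at chromosome 18, rose by 2.83 ± 0.40. Dmkn, Lce1f and Kprp also rose, by 2.65 ± 0.47, 2.61 ± 0.64 and 2.59 ± 0.54. Of the 15 suprabasal keratinocyte and cornified envelope genes, 6 rose and 9 did not pass, while all 15 rose when adjusted over the list alone. Their median was 2.25, with camera adjusted p = 2.24e-13, adjusted p = 0.383 with an estimated correlation and fry adjusted p = 0.018, or 0.187 without Control 1. Hrnr, Tgm3 and Dsg1a rose by 2.11 ± 0.39, 2.12 ± 0.41 and 2.34 ± 0.52. Of 10 basal keratinocyte markers, Krt14 rose by 1.28 ± 0.25 and 9 did not pass. Among gene ontology terms, the cornified envelope held 25 of the 368 annotated higher genes where 1.8 were expected, adjusted p = 2.36e-19 by the hypergeometric test. That test takes genes as independent, which these are not, so its p is too small.

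Of 11 heat shock and endoplasmic reticulum stress genes 3 rose, the chaperone genes Dnajb1 by 0.67 ± 0.15, Hspa1b by 1.25 ± 0.29 and Hspa1a by 0.98 ± 0.25. The camera adjusted p of that list was 0.00335, adjusted p = 0.383 with an estimated correlation, and the fry adjusted p was 0.0209, or 0.134 without Control 1 and 0.0847 without Control 2. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. Of 11 immediate early genes, Fosb rose by 2.09 ± 0.49 and 10 did not pass. The list's fry adjusted p was 0.313.

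Transcripts of the mitochondrial genome were lower in the mean of the spacer groups, although D15L100 overlapped Control. Their share of all FPKM was 12.54, 10.74 and 7.4% in Control 1, 2 and 3, and 8.09, 5.18 and 9.09% in D15L100 1, 2 and 3. ATP8 fell by 1.59 ± 0.30 on the log2 scale, ND2 by 1.33 ± 0.30, ATP6 by 1.31 ± 0.27, ND4L by 1.29 ± 0.28 and ND1 by 1.22 ± 0.25. COX2, COX3 and ND5 fell by 1.20 ± 0.26, 1.13 ± 0.24 and 1.10 ± 0.25. ND1, at 2751 to 3707 of the mitochondrial genome, averaged 9660 ± 4143 FPKM in Control and 3090 ± 317 in D150L150. Of 13 mitochondrially encoded genes, a set chosen after their values were seen, 11 fell, and none passed without Control 1. ATP8 and ATP6 overlap, so fragments of one cannot always be told from those of the other. The respirasome term held 8 of 95 lower genes where 0.5 were expected, adjusted p = 5.02e-05 by the hypergeometric test. All 8 are mitochondrially encoded and vary together, while the test takes genes as independent, so its p is too small. The list of nuclear oxidative phosphorylation genes had a level difference of -0.42 in the same direction but did not pass. Its exact permutation p was 0.113, adjusted p = 0.309. The serine protease inhibitor Serpine2 fell by 1.07 ± 0.24, and the connexin gene Gja4 was 2.22-fold lower.

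None of the 15 endothelial markers tested passed over all genes, although all 15 had negative values, with a median of -0.80. Tek, an endothelial receptor, had -0.61 ± 0.16 (adjusted p = 0.0538) and Cldn5 -0.82 ± 0.25 (adjusted p = 0.0763). When adjusted over the list alone, 10 fell. The camera adjusted p was 5.98e-06, adjusted p = 0.604 with an estimated correlation, and the fry adjusted p was 0.111. None of 11 pericyte and smooth muscle markers passed, with a median of -0.53, fry adjusted p = 0.0435 and adjusted p = 0.473 for camera with an estimated correlation. Leaving out Control 1, 2 or 3, D15L100 2, D15L200 1 or 2, or any 1 D150L150 library took that fry value to 0.0513 to 0.295. Among 15 skeletal muscle markers none passed, with a median of -0.88 and a fry adjusted p of 0.42. Muscle RNA varied widely within groups. Acta1, the skeletal muscle actin, ranged from 2923 to 5450 FPKM in Control and from 945.7 to 4225 in D100L150.

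**Figure D1:**
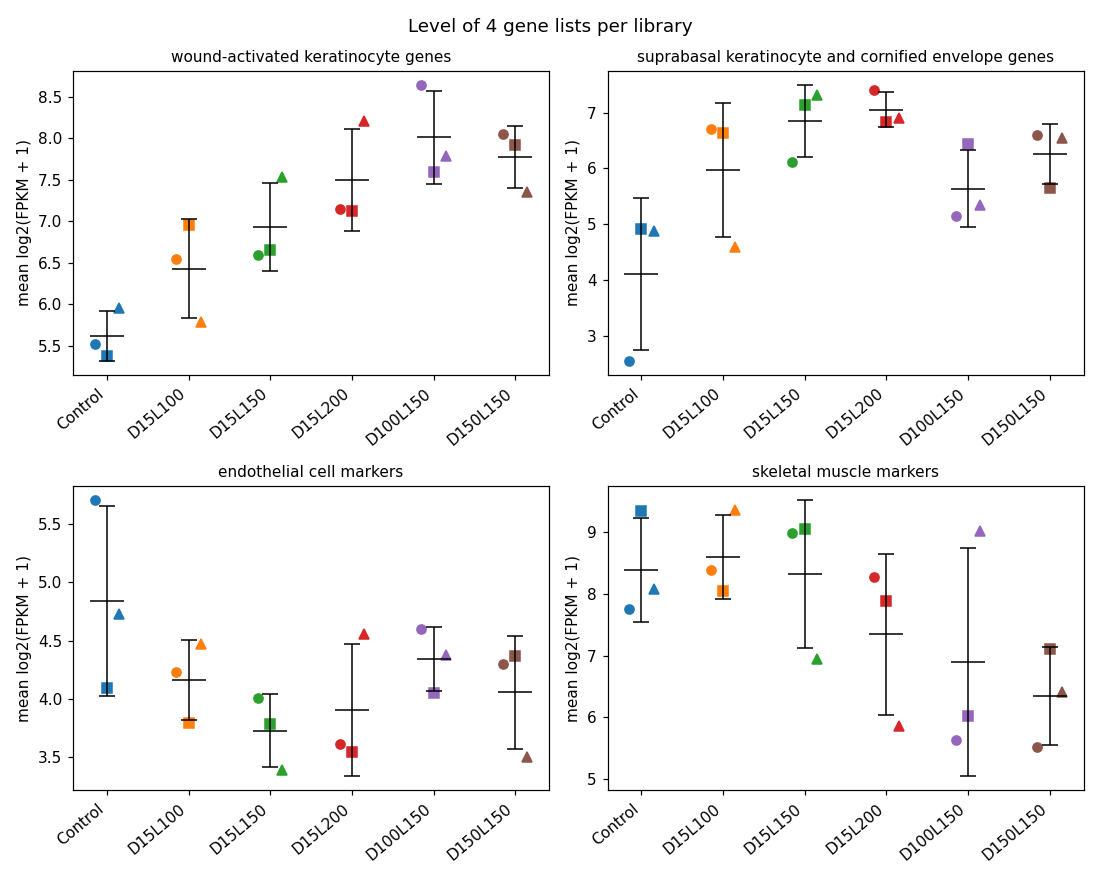
Mean log2(FPKM + 1) of the members of 4 gene lists in each of the 18 libraries, with group means and SD (n = 3, markers give the replicate number). The wound-activated level lies at 5.37 to 5.95 in Control and above the highest Control value in 14 of 15 spacer libraries; Control 1 is lowest in the suprabasal list at 2.54.

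In total 466 genes differed between the mean of the spacer groups and Control, 371 higher and 95 lower, with 2926 at an unadjusted p under 0.05 where 654 are expected by chance. The count rested on Control 1, since leaving it out gave 0 calls, and it was 279 without Control 2, 302 without Control 3, 279 without D15L200 1 and 302 without D150L150 1. Control 1 stood apart, at -69.9 on the first principal component against 1.3 and -13.9 in Control 2 and 3. Its log2 values correlated at 0.967 and 0.975 with Control 2 and 3, which correlated at 0.991 with each other. The count was 227 with no filter on low values, 271 by voom and 168 with the skeletal muscle level as a covariate. With that covariate all 466 genes kept their direction, and their median size went from 1.14 with a median SE of 0.25 to 1.04 with 0.23. Genes picked as called in these libraries were likely to keep their direction, here and in the groups below, so this is no further support. Camera called 16 of 41 lists, 0 with an estimated correlation, and 27 of 100 splits of the libraries reached 16.

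The comparison of D15L200 with Control called 204 genes, 187 higher and 17 lower. Lypd5 rose by 3.69 ± 0.73, from 7.74 ± 5.51 to 93.8 ± 1.72 FPKM (SD, n = 3). Cdsn rose by 3.48 ± 0.64, Klk10 by 3.29 ± 0.64, Kprp by 3.24 ± 0.70, Klk5 by 3.21 ± 0.61, Rptn by 3.18 ± 0.69 and Dmkn by 3.13 ± 0.61. Lce1g rose by 3.11 ± 0.67 and Il36rn, an antagonist of interleukin 36, by 3.01 ± 0.69, and Dsc1 was 9.17-fold higher. Of 13 wound-activated keratinocyte genes 6 rose, among them Krt6a by 2.15 ± 0.33 and Gjb2 by 2.59 ± 0.42. Of 15 suprabasal genes 3 rose, Dsc1, Hrnr by 2.89 ± 0.50 and Tgm3 by 2.34 ± 0.52. The fry adjusted p was 0.0157 and 0.0186 for these lists, and adjusted p = 0.329 for both by camera with an estimated correlation. Without Control 1 the fry values were 0.0827 and 0.104 and without D15L200 3 0.0565 for both, and the suprabasal one was 0.093 without D15L200 1. ATP8 fell by 1.85 ± 0.39, ND2 by 1.72 ± 0.39, ND4L by 1.60 ± 0.36, ND1 by 1.53 ± 0.32 and COX1 by 1.14 ± 0.26, and Rasl12 fell by 0.80 ± 0.19. COX1 was at 0 under quantile scaling, which gives the top-ranked gene of every library 1 value. No call was left without Control 1, without Control 2, without any 1 of the D15L200 libraries, or with no filter on low values. There were 22 with the skeletal muscle level as a covariate, where all 204 genes kept their direction. Their median size went from 1.83 with a median SE of 0.37 to 1.65 with 0.35.

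In D100L150, 181 genes differed from Control, 139 higher and 42 lower, a share of 76.8% higher that was 87.3% under quantile scaling. Klk10 rose by 3.69 ± 0.64, Lypd5 by 3.55 ± 0.73 and Klk6 by 3.53 ± 0.50, from 37.4 ± 23.4 to 370 ± 82.4 FPKM (SD, n = 3). The cornified envelope precursors Sprr2d and Sprr1a rose by 3.39 ± 0.71 and 2.98 ± 0.56, the glutathione transferase gene Gsta4 by 3.15 ± 0.62, Lce3f by 3.07 ± 0.51 and Spink5 by 3.04 ± 0.58. Of 13 wound-activated keratinocyte genes 10 rose, with Gjb2 at 3.12 ± 0.42, Krt6b at 3.12 ± 0.45 and Krt6a at 2.67 ± 0.33. The fry adjusted p of that list was 0.00183, and adjusted p = 0.241 by camera with an estimated correlation. Of 10 basal markers, Krt14 and the laminin gene Lama3 rose by 1.57 ± 0.32 and 1.84 ± 0.39. ATP8 fell by 1.89 ± 0.39. Igfbp5, an insulin-like growth factor binding protein gene, fell by 1.45 ± 0.33, from 148 ± 32.2 to 56.4 ± 24.0 FPKM. Orm2, Gprc5c, Tbx2, Mylk and Rasl12 fell by 1.54 ± 0.35, 1.10 ± 0.25, 1.04 ± 0.23, 1.00 ± 0.23 and 0.95 ± 0.19, and Musk, a receptor of the neuromuscular junction, by 0.95 ± 0.20. No call was left without Control 1 or without D100L150 1, or with only the compared groups in the fit. Fewer genes were called with the skeletal muscle level as a covariate, where all 181 kept their direction. Their median size went from 1.66 with a median SE of 0.33 to 1.43 with 0.32. The number of calls was 40 without Control 2, 304 without D100L150 2 and 307 without D100L150 3.

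**Figure D2:**
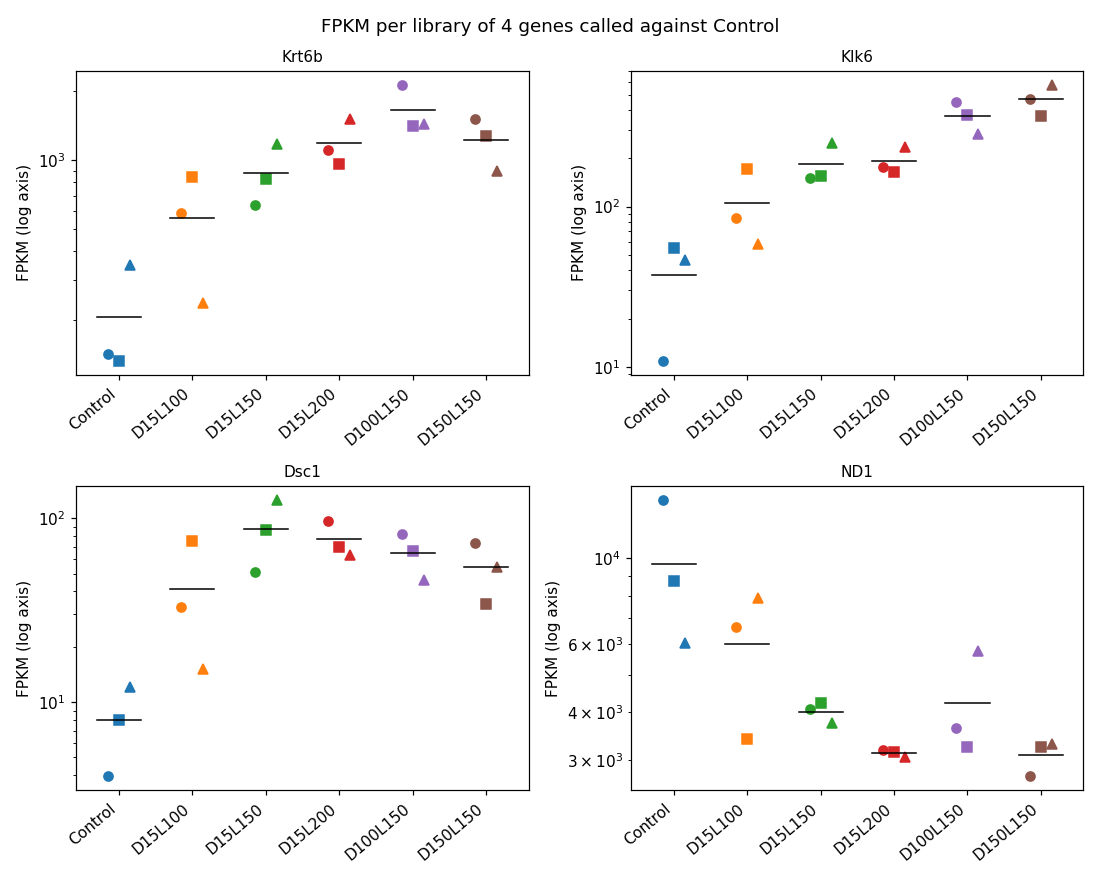
FPKM of Krt6b, Klk6, Dsc1 and ND1 in each library on a log axis, with the group mean as a line (n = 3, markers give the replicate number). Krt6b lies at 132.4 to 348.1 in Control and 1405 to 2136 in D100L150, and ND1 at 6053 to 14180 in Control and 2727 to 3303 in D150L150.

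In D150L150, 317 genes differed from Control, 265 higher and 52 lower. Klk10 rose by 4.06 ± 0.64, Klk6 by 3.88 ± 0.50, Fosb by 3.36 ± 0.64, Lypd5 by 3.35 ± 0.73, Spink5 by 3.06 ± 0.58, Sprr1a by 3.05 ± 0.56 and Klk7 by 3.00 ± 0.49. Sprr2a2 and Sprr2d, which belong to a family of similar genes, rose by 3.19 ± 0.58 and 2.88 ± 0.71, and Cdsn by 2.97 ± 0.64. Of 13 wound-activated keratinocyte genes 10 rose, including Krt17 by 2.46 ± 0.40, with fry adjusted p = 0.00446 and adjusted p = 0.525 by camera with an estimated correlation. Of 10 basal markers, Krt14 rose by 1.63 ± 0.32 and Lama3 by 1.62 ± 0.39. ND4L fell by 1.89 ± 0.36, ATP8 by 1.86 ± 0.39, ND2 by 1.85 ± 0.39, ATP6 by 1.61 ± 0.35 and ND1 by 1.56 ± 0.32. Coro6 fell by 1.78 ± 0.41, Sgca, a sarcoglycan gene, by 1.76 ± 0.42, and Scx, a tendon transcription factor gene, by 1.53 ± 0.38. None of 15 skeletal muscle markers passed over all genes, although all 15 had negative values, with a median of -1.93. When adjusted over the list alone, 7 fell, and the fry p was 0.0435, adjusted p = 0.221. Acta1 was at 1033 ± 324 FPKM against 3826 ± 1409 in Control, -1.88 ± 0.61, adjusted p = 0.115. With the skeletal muscle level of each library as a covariate no call was left. All 317 genes kept their direction and an unadjusted p under 0.05, which was likely beforehand, as they were picked as called in these libraries. Their median size went from 1.54 with a median SE of 0.32 to 1.23 with 0.34, and the smallest adjusted p was 0.0816. There were 2 calls without Control 1, 0 without D150L150 1, 30 without D150L150 3, 110 without Control 2 and 148 without D150L150 2.

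D15L150 and D15L100 had no gene past the threshold against Control. In D15L150, 2585 genes had an unadjusted p under 0.05 where 654 are expected, and the smallest adjusted p was 0.0525 in limma. Voom on the recovered fragments also called 0. Dsc1 was higher by 3.32 ± 0.51, Hrnr by 2.79 ± 0.50, Krt6b by 2.18 ± 0.45, the inner root sheath keratin Krt28 by 1.62 ± 0.25 and the hedgehog receptor gene Ptch1 by 0.73 ± 0.13, each with adjusted p = 0.0525. By fry, 5 lists passed. These were suprabasal genes (median 2.66, adjusted p = 0.0297), wound-activated genes (1.61, adjusted p = 0.0443), hair shaft and root sheath genes (1.33, adjusted p = 0.0274), WNT and hedgehog genes (0.55, adjusted p = 0.0297) and lymphatic endothelial markers (1.29, adjusted p = 0.0445). The hair shaft result rests on the 4 of 21 list genes that passed the filter on low values, Krt28, Dlx3, Tchh and Msx2. The lymphatic one rests on 5 of 7 genes, of which 3 had positive and 2 negative values. Krt28 averaged 2.42 FPKM in D15L150 and 0.425, 0.292, 0.103 and 0.186 in D15L100, D15L200, D100L150 and D150L150. It passed the filter only through D15L150, so the filter itself favours a higher value there. Without D15L150 2, in which the root sheath keratin gene Krt71 was at 18.83 FPKM against at most 0.5331 elsewhere, the hair shaft median was 0.85 with adjusted p = 0.0487, and the suprabasal and wound-activated lists had adjusted p = 0.0557. None of the 5 lists passed without Control 1 (adjusted p = 0.135 each) or without D15L150 3 (0.0583 to 0.181). The WNT and hedgehog list was at 0.0639 without Control 3, the wound-activated list at 0.0879 without Control 2, and the lymphatic list at 0.116 without Control 2 and 0.147 without D15L150 1. By camera with an estimated correlation none passed, with a smallest adjusted p = 0.323. The gene count was 28 with a pseudocount of 0.1, 88 under quantile scaling, 142 under TPM scaling and 45 without D15L150 1. In D15L100, 431 genes had an unadjusted p under 0.05, fewer than the 654 expected, voom also called 0, and no list passed by fry. Dsc1 was at 41.1 ± 30.9 FPKM against 8.0 ± 4.1 in Control, 2.06 ± 0.51, adjusted p = 1.

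The lists of higher genes of the groups with calls overlapped. D15L200 and D100L150 shared 91, D15L200 and D150L150 139, and D100L150 and D150L150 123, and 90 were in all 3. Independent lists would share 2, 3.8 and 2.8. In 20 simulations, unchanged groups were compared with 1 shared set of simulated controls. Lists of the same lengths, made of the higher genes with the smallest p, shared 32.9, 42.7 and 35.5 on average and at most 77, 116 and 72. Of the lower genes these pairs shared 5, 15 and 13, with 3 in all 3 groups, where simulated lists shared at most 9, 10 and 20. The simulated controls mixed the deviations of all 18 libraries from their group means, so the real Control 1 was not kept in them. The 3 Control libraries cannot be split, so part of the excess may come from the shared controls, which the simulated maxima do not bound. Without Control 1 the 3 groups had 0, 0 and 2 calls.

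Spacer groups were then compared with each other, which asks whether the second number (100, 150 and 200 at D15) or the first (15, 100 and 150 at L150) goes with a difference. No gene passed in either series or any of the 6 pairs in limma. In the series at D15, 378 genes had an unadjusted p under 0.05, and the lowest p-values were those of Krt28, Krt2 and Lce3f (adjusted p = 0.784 each). The rank of Krt28 is no independent result, as it passed the filter on low values only through D15L150. Krt2, a keratin of the upper epidermis, was at 7.29 ± 4.51 FPKM in D15L150, 0.47 ± 0.78 in D15L100 and 1.03 ± 1.13 in D15L200 (SD, n = 3). Unadjusted counts for the pairs at D15 were 617 for D15L150 against D15L100, 96 for D15L200 against D15L150 and 678 for D15L200 against D15L100.

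In the series at L150, 751 genes had an unadjusted p under 0.05. Krt2 and Krt28, of which Krt28 passed the filter on low values only through D15L150, came first with adjusted p = 0.131. Krt2 was at 0.11 ± 0.16 FPKM in D100L150 and 0.11 ± 0.09 in D150L150. Ptch1 (adjusted p = 0.219), at chromosome 13, 63508328 to 63573460 in GRCm38, was at 3.43 ± 0.75 FPKM in D15L150, 1.48 ± 0.19 in D100L150 and 1.76 ± 0.36 in D150L150. Gli1, a transcription factor gene of the hedgehog pathway (adjusted p = 0.296), was at 3.06 ± 0.63, 0.44 ± 0.36 and 1.27 ± 0.41 FPKM. The fatty acid transporter gene Cd36 was at 60.1 ± 11.4 FPKM in D15L150, 110 ± 17.6 in D100L150 and 55.3 ± 14.4 in D150L150. Unadjusted counts for the pairs at L150 were 1492 for D100L150 against D15L150, 288 for D150L150 against D100L150 and 648 for D150L150 against D15L150. Voom called 0 in all 6 pairs and both series, whereas library weights, an alternative chosen after seeing the data, called 1026 genes in the series at L150 and 2536 for D150L150 against D15L150. The weights were 3.8, 1 and 0.47 for D150L150 1, 2 and 3, and 1.16, 3.92 and 0.44 for D15L150 1, 2 and 3. The weighted counts for this pair thus rest mostly on 1 library of each group.

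**Figure D3:**
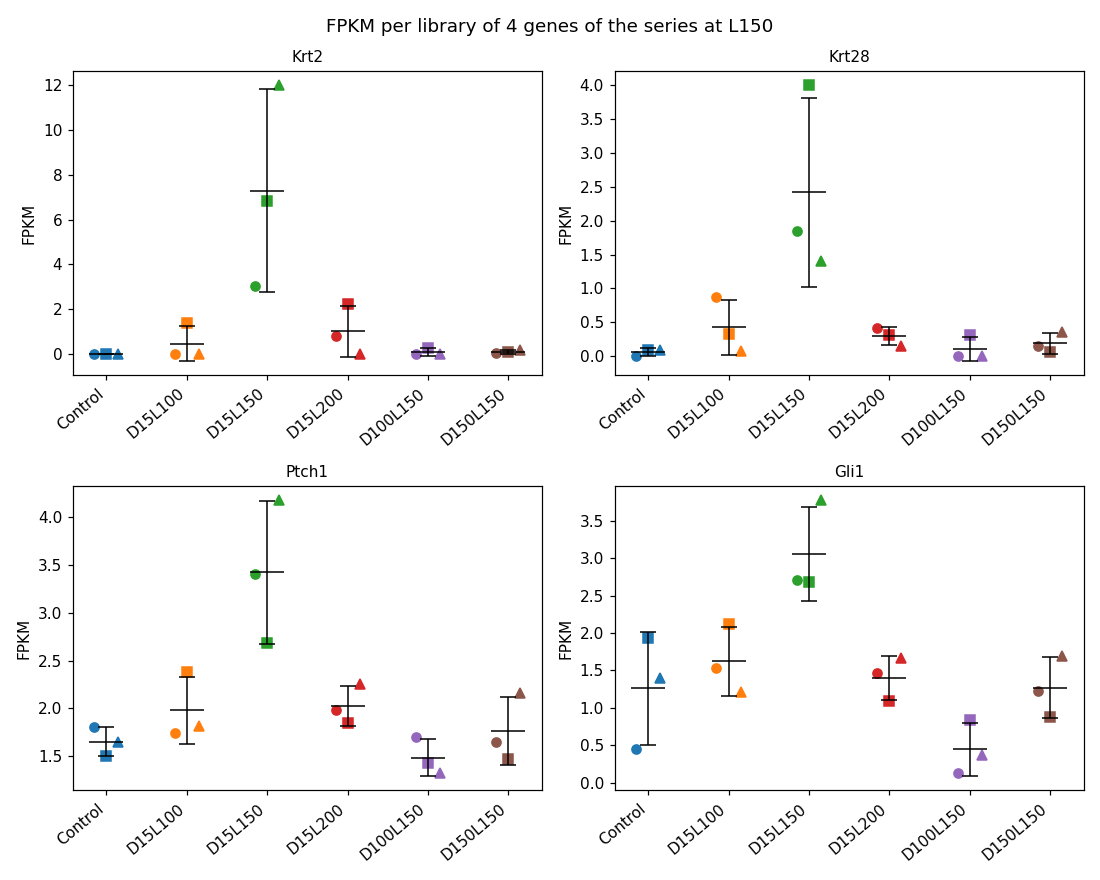
FPKM of Krt2, Krt28, Ptch1 and Gli1 in each library, with group means and SD (n = 3, markers give the replicate number). The 3 D15L150 libraries lie at 2.675 to 3.778 for Gli1, above all other libraries, of which the highest is at 2.121; none of the 4 genes passed in the series at L150.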

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

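The tests on the share of hair follicle and without D15L150 2 were chosen after related values had been seen. The bound for the test without D100L150 1 was written before that test was run, although the pattern itself was found in these data. The WNT and hedgehog pathway genes differed between D100L150 and D15L150, groups measured against the same Control, by a test of the difference itself. The fry adjusted p was 0.027 over the 41 lists of this pair, but 0.162 when adjusted over the 246 tests of all 6 pairs of spacer groups. The camera adjusted p was 0.00122, but adjusted p = 0.403 with an estimated correlation. The median was -0.50 in D100L150 against D15L150. Gli1 had -1.51 ± 0.25 and Ptch1 -0.82 ± 0.13, each with adjusted p = 0.0833 in limma, and Axin2 -1.04 ± 0.29 with adjusted p = 0.412. Over all 3 groups at L150, the exact permutation p of the list level was 0.00357, adjusted p = 0.146. Without D100L150 1 the median was -0.30 with a fry p of 0.00408, and without D15L150 2, which stands apart in the root sheath keratin gene Krt71, it was -0.33 with a fry p of 0.00136, which argues against either library as the whole source. Over the 41 lists the adjusted p was then 0.167 and 0.0558, and it was 0.0933 without D15L150 3 and 0.103 without D100L150 3, so the call rests on each of these 4 libraries. A smaller share of hair follicle in D100L150 stays open: the hair follicle stem cell list had a median of -0.36 with a fry p of 0.0622. The hair shaft and root sheath list, with 4 of 21 genes tested, had a median of -0.77 with a fry p of 0.00585, adjusted p = 0.12 over the lists of this pair, and its member Krt28 had -1.57 ± 0.25 with adjusted p = 0.0833 in limma. As Krt28 passed the filter on low values only through D15L150, the filter favours this direction. An effect of the spacers, which the design names, also stays open, as untested. An exact permutation of 3 against 3 libraries cannot go below 0.1, so this pair alone has no such test.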

How the results depend on the processing

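No gene named in a comparison of 2 groups or of the mean turned its direction under any setting run, with COX1 at 0 under quantile scaling. Of 116 called values of named genes, 110 kept their call with a pseudocount of 0.1, 104 with quantile scaling, 40 with no filter and 1 with the 3 libraries left out; when leaving out 1 library 659 of 1092 did. Leaving out 1 library gave 0 to 160 genes for D15L200 (204 with all libraries), 0 to 307 for D100L150 (181), 0 to 274 for D150L150 (317), 0 to 597 for the mean of the spacer groups (466), 0 to 45 for D15L150, 0 to 1 for D15L200 against D15L100 and 11 to 18 for the lists of the mean comparison (16). The runs without Control 1 gave 0, 0, 2 and 0 for the first 4, and D150L150 gave 0 without D150L150 1. Runs that leave out 1 library assume that the remaining 2 of a group vary like the other groups. With the 3 libraries of highest cytokine level left out, D15L200, D100L150, D150L150 and the mean gave 0, 0, 2 and 0. With no filter they gave 0, 50, 82 and 227, with 1 for D15L100, 3 for D15L150 against D15L100, 2 for D15L200 against D15L100, 2 for D150L150 against D15L150 and 3 for the series at D15. With only the groups compared in the fit, D15L200, D100L150, D150L150 and D15L200 against D15L100 gave 52, 0, 47 and 1. D15L150 gave 28 with a pseudocount of 0.1, 88 with quantile scaling and 142 with TPM scaling. With the skeletal muscle covariate D15L150, D15L200, D100L150, D150L150 and the mean gave 134, 22, 23, 0 and 168, and D100L150 against D15L150 gave 1. Genes called without it in D15L200, D100L150, D150L150 and the mean all kept their direction, which was likely, as they were picked in these libraries. Their median sizes went from 1.83, 1.66, 1.54 and 1.14 to 1.65, 1.43, 1.23 and 1.04. Voom gave 10, 91, 171 and 271 for D15L200, D100L150, D150L150 and the mean. Library weights gave 538 for D15L150, 921 for D15L200, 1939 for D150L150, 1 for D15L200 against D15L150, 5 for D100L150 against D15L150, 2 for D150L150 against D100L150, 2536 for D150L150 against D15L150, 1 for the series at D15 and 1026 for the series at L150. The weights rested mostly on 1 library in D15L150 (3.92 for D15L150 2), D15L200 (4.02 for D15L200 2) and D150L150 (3.8 for D150L150 1), and Control 1 had 0.24. With an estimated correlation 0 of the lists passed. The cause of these changes was not tested. Covariate, weights, voom and the 3 left-out libraries were chosen after seeing the data.

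With the replicate number as a block, D15L200, D100L150, D150L150 and the mean gave 0, 46, 105 and 256 genes. The numbers do not pair the libraries: 18 of 45 same-numbered pairs correlated above 0.1, from -0.66 to 0.53, and 6 of 18 libraries correlated best with their own number.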

Other observations

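The tests on the keratinocyte pattern, the test of the mitochondrial pattern without Control 1 and the counts of splits were chosen only after their results, or values close to them, had been seen. Erythroid genes, lymphatic endothelial markers and mast cell markers had positive medians in the mean of the spacer groups, 1.12, 0.74 and 1.46, and fry adjusted p-values of 0.313, 0.0521 and 0.194, so that none passed. The lymphatic chemokine gene Ccl21a was at 9.34 ± 6.13 FPKM in Control, 46.7 ± 9.68 in D15L150 and 46.1 ± 7.26 in D15L200 (SD, n = 3). Hbb-bs, a beta globin gene with near-identical copies, was at 746 ± 664 FPKM in D100L150 and 123 ± 119 in Control.

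Libraries of 1 group differed in inflammation, as values chosen after they were seen. Il1b, an inflammatory cytokine gene, was at 564.3 FPKM in Control 1, 678.4 in D15L200 3 and 689.7 in D100L150 1, and at 19.98 to 309.8 in the other 15 libraries. Arg1, an arginase gene of repair macrophages, reached 1754 FPKM in D100L150 1. Krt71, an inner root sheath keratin gene, was at 18.83 FPKM in D15L150 2 and at most 0.5331 elsewhere.

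The higher keratinocyte genes of the spacer groups were weighed against a single Control library and against a larger share of epidermis alone. Without Control 1 the wound-activated level was still higher by 1.67, against 1.71 with it, and the exact permutation p over 136 splits was 0.0147, which argues against that library as the source of this list's difference, although not of the gene counts. The suprabasal difference went from 2.25 to 1.47. A larger share of epidermis alone would raise basal and wound-activated genes alike if both lists were equally confined to epidermis, which was not tested. They moved apart by 0.90 with an exact permutation p of 0.0355, unadjusted. The basal level itself was higher by 0.81, with an exact permutation p of 0.0196, adjusted p = 0.134. The test therefore cannot decide, and a larger share of epidermis stays open. An effect of the spacers, which the design names, stays open, as does a difference in the depth or place of sampling; neither was tested.

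The lower mitochondrially encoded transcripts had a median of -1.19 over 13 genes, with a median SE of 0.26 and 11 calls. Less skeletal muscle might lower them, but with the muscle level as a covariate the median was -1.01 with an SE of 0.25 and 6 calls. Without Control 1 it was -0.89 with an SE of 0.29 and 0 calls, as both a smaller fold and fewer libraries raised the p-values. These values argue against either as the whole cause. The bound for muscle was written before its test was run, but the 13 genes and the covariate were chosen after seeing the data. Differences in RNA handling or in dying cells were not tested and stay open.

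Other splits of the libraries were compared with the real ones. For the mean of the spacer groups, 2 of 100 splits gave as many genes as the real 466, itself included, a share under 0.05. As these counts were chosen after being seen and the real one fell to 0 without Control 1, this share does not exclude chance. The highest other split gave 1311. That split set D15L200 3, D100L150 1 and D150L150 1 against the other libraries. These had the highest values of the 18 libraries on the second principal component, 33.7, 53 and 31.3, which holds 29% of the variance. The count points to a structure of the libraries beyond the groups, whose cause was not tested. For the lists of that comparison, 27 of 100 splits gave as many calls as the real 16, up to 24, so chance is not excluded for the camera count. For the series the real count was 0, and all 100 splits gave as many, with a highest other of 0 for the series at D15 and 226 for the one at L150. The 10 splits of 3 against 3 are too few for a share under 0.05. There the real and highest other counts were 204 and 0 for D15L200, 181 and 0 for D100L150, 317 and 1 for D150L150 (as large in 1 split each), and real counts of 0 in the other 8 pairs, where all 10 splits gave as many and the highest other was 240 for D100L150 against D15L150, 12 for D150L150 against D100L150, 1 for D15L200 against D15L100 and 0 for the other 5.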
